A study of Homo sapiens with 16 samples.

How the data were processed

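Chromatin accessibility was measured by ATAC-seq, in which the Tn5 transposase tags open chromatin. The cells came from brain organoids grown from H9, an established human embryonic stem cell line, that had been given 2 reporters. EGFP was joined to the end of the coding sequence on one SOX2 allele, so that cells expressing this neural progenitor gene were green. dTomato under the promoter of the synaptic vesicle gene SYN1 was placed at AAVS1, a site inside PPP1R12C, so that neurons were red. Green and red cells were sorted from organoids enriched for dorsal telencephalon, the part of the forebrain that forms the cerebral cortex, on days 40, 60, 90 and 120. Per the labels' protocol, isolated nuclei were treated with Tn5 for 30 minutes and libraries were made with unique dual indices.

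Each of the 8 groups, a population at a stage, had 2 libraries, and each of the 16 libraries had its own list of broad peaks. Groups and replicate numbers were taken from the sample titles and the labels for stage and cell type. Per the submitters' processing notes, the tools were Trim Galore 0.5.0, BWA 0.7.17, Picard, SAMtools 1.9 and MACS2 2.1.2, with the build hg38. Settings for duplicates, mitochondrial reads, the Tn5 offset and excluded regions are not given in the sources used here. The deposited lists give a score for each peak in column 5, the form in which MACS2 writes an integer from its q-value. The deposited ratio in column 7 is the fold enrichment of the peak over its background as the authors' peak caller gave it. The deposited −log10 p-values and −log10 q-values stand in columns 8 and 9. These values belong to the authors' own calls and were used only to rank or filter peaks within 1 list.

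The lists hold no read numbers, so the depth of each library is unknown, and no counting interval or floor could be given. What the files show is how much was called, from 68364 to 138554 peaks per library, and the lowest −log10 q in each list lay between 1.00 and 1.01. Because each list was called on its own, a deeper or cleaner library can list more and wider peaks. Only the presence and the extent of peaks were compared between libraries, and the amount called is given beside each count that moves with it. Peaks on chromosomes 1 to 22 and X were used, which left out between 95 and 387 peaks per library.

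The reference was a table of RefSeq genes of GRCh38.p14, which has the coordinates of hg38. It gave the start and end of 19974 protein-coding genes but no strand, exons or sequence. Windows of 1 kb around either end of a gene therefore took the place of windows around transcription start sites, and positions are described only as inside a gene, outside genes or near a gene end. Motif density in distal peaks had been planned and was not run, since no genome sequence was used here. All 269 entries of the gene lists matched the table, 1 of them through an older symbol.

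Similarity of 2 lists was the Jaccard index of covered bases. Regions were the union of all peaks, merged where they overlapped by at least 1 base, and a library had a region when any of its peaks overlapped it by at least 1 base. Regions with a peak in 2 to 14 libraries were tested with Fisher's exact test, two-sided, 8 progenitor against 8 neuron libraries, with Benjamini-Hochberg adjustment. With 2 libraries against 2 at a stage, and with 4 against 4 within a population, counts of regions that follow the groups were set beside the counts that other splits of the same libraries gave. Splits that keep the 2 libraries of each group together, 35 between the populations and 3 within one, were added after the data were seen.

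Locus coverage was the number of bases covered by peaks in a gene and 20 kb on either side. It was taken as log2 of the bases plus 500, minus the log2 of the library's total of covered bases, so a difference is on the log2 scale with that pseudocount. The pseudocount shrinks the change of sparsely covered genes. Because the total is subtracted afterwards, a locus without covered bases takes a higher value in a shorter list. SLFN12, with no covered bases in late progenitors, stood at 8.57 at day 90 and 9.42 at day 120. Differences of sparsely covered genes can therefore also arise from the amount called. Genes with at least 500 covered bases in at least 2 libraries were kept, 18755 in all. They were fitted with limma 3.58.1 in R 4.3.3, with a trend in the prior variance, in 1 fit of 8 group means. Contrasts were progenitors minus neurons over the stages and at each stage, late (days 90 and 120) minus early (days 40 and 60) in each population, and the difference between these. Adjusted p-values are Benjamini-Hochberg values over all genes tested, with a threshold of 0.05. Windows of neighbouring genes overlap, so neighbours share values.

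The 24 gene lists were fixed before the data were examined, as were the tests and the rule for naming genes. They were radial glia, outer radial glia, intermediate progenitor and proneural, cell cycle, Notch pathway, Hippo-YAP targets and effectors, pan-neuronal, synaptic vesicle and release, glutamatergic neuron, ion channel, axon guidance and adhesion, deep-layer neuron, upper-layer neuron, GABAergic and ventral, astroglia, oligodendrocyte lineage, choroid plexus and cortical hem, mesenchyme and fibroblast, immune and endothelial, non-telencephalic neural, pluripotency, early temporal, late temporal, and housekeeping. A list's score in a library was the mean scaled log2 coverage of its members minus the mean of all genes tested. Scores were compared by two-sided exact permutation tests, adjusted over the 24 lists within each comparison. The smallest p these tests can give is 0.000155 for 8 against 8 libraries and 0.0286 for 4 against 4. They treat libraries as exchangeable, although the 2 libraries of a group were alike on average, so their p-values may be too small. Splits that keep the libraries of a group together were not run for the scores.

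Genes were named by rule. The reporter loci came first. Within a list, up to 4 members that passed the test with the largest absolute log2 difference were named. The member with the largest difference among those that did not pass was named only where the text speaks of such members. Some members count in their lists while their own values are not reported here. Over all genes, the 10 per direction with the largest difference between the populations were named among those that passed and had the same direction at all 4 stages, and for late against early the 5 per direction and population. Of the regions that passed, those with the smallest p that lay closest to an end of a gene of the lists were named, 5 per direction and at most 1 per gene.

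The limma step was tested on simulated data with the real genes. For progenitors against neurons over 18755 genes, it recovered 29 of 100 loci changed by 0.5 on the log2 scale and 87 of 100 changed by 1, with 6 unchanged loci called, and called none when nothing had been changed. The region test recovered 4596 of 5000 simulated regions among 182575, with 24 unchanged regions called. The simulated regions had a peak in 97% against 3% of libraries, so weaker differences were not tried. Both simulations drew libraries independently, without likeness between replicates of a stage. Their few false calls therefore need not hold for these data. Other steps ran in Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.

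Alternatives fixed before the data were examined were lists shortened to the 68364 peaks with the highest −log10 p, peaks with −log10 q of at least 3, each library left out in turn, at least 50% of a region covered, windows of 500 bases, permutation within stage, the replicate number as a block, flanks of 5 and 50 kb, pseudocounts of 100 and 2000 bases, no filter, scaling by the median or none, the number of peaks in place of bases, gene-end windows of 2.5 kb, and distal peaks only. Alternatives chosen after the data were seen were scaling before the pseudocount was added, the amount called as a covariate, and all results without the 2 libraries with the shortest lists, progenitor day 120 replicate 2 and neuron day 60 replicate 2.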

Results

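Open chromatin was mapped in 16 libraries from H9-derived brain organoids, 8 from sorted SOX2-EGFP-positive progenitors and 8 from sorted hSYN1-dTomato-positive neurons. Each population was taken at days 40, 60, 90 and 120, with 2 libraries per population and stage. The question the design poses is which regions are open in neural progenitors and in the neurons formed from them, and how this changes as the tissue ages. The labels do not say whether the 2 libraries of a group came from separate cultures, so the p-values given here measure the spread between these libraries, which may be technical. In the text, ± is the SD over libraries for kilobases, percentages and scores, and the SE of the limma fit for log2 differences. Covered length per library ranged from 36.9 Mb in progenitor day 120 replicate 2 to 104 Mb in neuron day 40 replicate 1, and the read depth behind it is unknown.

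The populations did not differ detectably in how much was called. Progenitor lists held 108307 ± 18815 peaks and neuron lists 107699 ± 18026 (n = 8 each, two-sided exact permutation p = 0.949). These covered 81.2 ± 20.1 Mb in progenitors and 77.4 ± 18.4 Mb in neurons (n = 8 each, exact p = 0.691). Peaks within 1 kb of a gene end made up 13.7% ± 1.69 and 13.7% ± 1.72 of the lists (n = 8 each, exact p = 0.991). Between the stages of a population the amount differed more, as mean covered length went from 101 Mb in day 90 progenitors to 61.0 Mb in day 120 progenitors, and from 101 Mb in day 40 neurons to 59.3 Mb in day 120 neurons.

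The loci used for sorting were examined first. SOX2, the transcription factor that marks neural progenitors (chromosome 3, 181711925 to 181714436, hg38), and the 20 kb on either side of it had 13.3 ± 3.5 kb of peaks in progenitors and 5.59 ± 1.64 kb in neurons (n = 8 each). The ratio was 2.38 (exact permutation p = 0.000311), and the scaled log2 difference was 1.12 ± 0.13 (limma adjusted p = 1.1e-06), with values of 1.83, 0.88, 1.11 and 0.67 from day 40 to day 120. SYN1, which encodes the vesicle protein synapsin I (chromosome X, 47571901 to 47619857), had 3.30 ± 0.451 kb in progenitors and 3.01 ± 0.552 kb in neurons, with a log2 difference of 0.07 ± 0.14 (n = 8 each, limma adjusted p = 0.779, exact permutation p = 0.263). Reads from the inserted SYN1 promoter cannot be told from those of the gene itself in these lists. PPP1R12C, the gene that holds the AAVS1 site (chromosome 19, 55090918 to 55117637), had 2.74 ± 0.979 kb in progenitors and 3.58 ± 1.11 kb in neurons, with a log2 difference of −0.42 ± 0.15 (limma adjusted p = 0.043). The covered kilobases did not pass the exact permutation test (p = 0.136). The limma call was lost when any 1 of 10 of the 16 libraries was left out, with an adjusted p of up to 0.150. All 3 genes had a peak at a gene end in each of the 16 libraries.

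**Figure D1:**
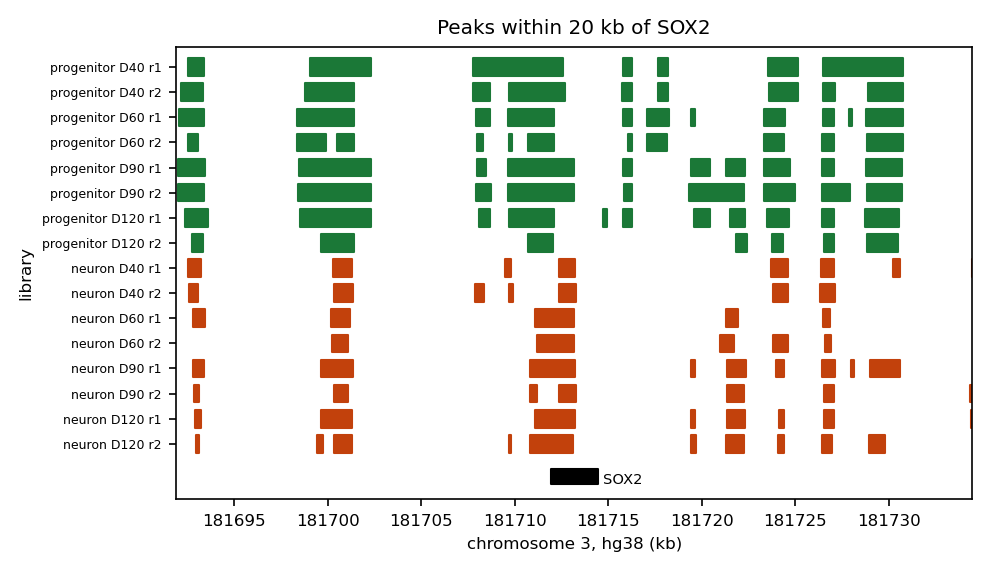
Peaks of each of the 16 libraries within 20 kb of SOX2, along chromosome 3 (hg38, kb), with progenitor peaks in green, neuron peaks in orange and the gene as a black bar. Peaks covered 7.10 to 18.0 kb of this window in progenitor libraries and 3.81 to 8.94 kb in neuron libraries.

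Libraries of 1 population shared more open chromatin than libraries of different populations. The Jaccard index of covered bases averaged 0.459 over the 28 pairs of progenitor libraries, 0.417 over the 28 pairs of neuron libraries and 0.326 over the 64 mixed pairs. The mean within populations exceeded the mean between them by 0.112 (n = 8 each, exact permutation p = 0.000155, the smallest that the test can give). This test treats all 16 libraries as exchangeable, which the likeness of replicates goes against, so its p may be too small. Replicate pairs were closer still on average, with a mean of 0.552 in progenitors against 0.443 for other pairs, and 0.532 in neurons against 0.398. Of the 105 ways to pair 8 libraries, the real one gave the highest mean in each population (exact p = 0.00952 in both). The progenitor day 120 pair was the least alike, at 0.363, below the mean of other progenitor pairs, and the progenitor day 90 pair the most alike, at 0.672. By day, the populations shared 0.357, 0.308, 0.397 and 0.322 of their bases.

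**Figure D2:**
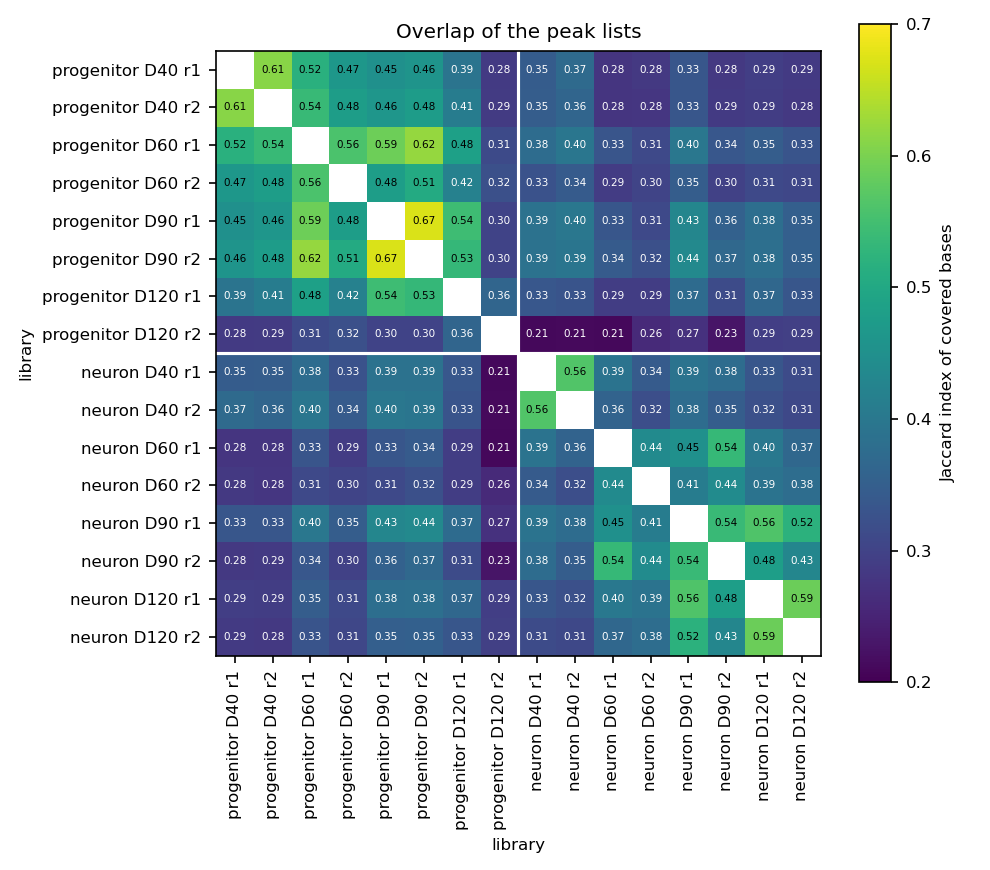
Jaccard index of covered bases for each pair of the 16 libraries, ordered by population and day, with the index printed in each cell and white lines between the populations. Pairs within progenitors ranged from 0.285 to 0.672, pairs within neurons from 0.309 to 0.587 and mixed pairs from 0.210 to 0.435.

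Many single regions had peaks in most libraries of 1 population and in few or none of the other. The merged peaks made 321056 regions, of which 24797 had a peak in all 16 libraries and 104970 in only 1 library. Among the 182575 regions tested, 5582 were called more often in progenitors and 2318 more often in neurons (Fisher's exact test, adjusted p below the threshold). In progenitors, 1871 of them had a peak in 8 of 8 libraries against 0 of 8 neuron libraries, and in neurons 540 had the mirror pattern. These regions lay away from gene ends, with 2.15% of the progenitor regions and 2.46% of the neuron regions within 1 kb of one, against 3.66% of the regions not called. The median distance to a gene end was 64.8 kb, 75.5 kb and 54.1 kb in the same order, values that were not tested. The counts depend on what is taken as open, since 714 and 155 regions were called when peaks had to cover at least 50% of a region. Without the 2 shortest lists 3407 and 816 were called, but there the smallest p that a region can reach is also higher. With stage as a stratum no region passed, with 19477 progenitor and 12720 neuron regions at an unadjusted p under 0.05 and a smallest adjusted p of 0.107 in the exact permutation test.

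Regions at ACSBG1, JAG1, VIM, DNMT3B and CSF1R were among those with a peak in 8 progenitor libraries and in 0 neuron libraries (Fisher's exact p = 0.000155, adjusted p = 0.0118 for each region named here). One overlapped an end of ACSBG1, an acyl-CoA synthetase gene of astrocyte-like cells (chromosome 15, 78234180 to 78235103), and another an end of the Notch ligand gene JAG1 (chromosome 20, 10636603 to 10638174). A region 490 bases outside VIM, the gene of the radial glial filament protein vimentin, spanned 17238084 to 17239520 on chromosome 10. Inside the DNA methyltransferase gene DNMT3B, 574 bases from its end, 32807367 to 32808782 on chromosome 20 was open in progenitors. The region at 150112424 to 150113122 on chromosome 5 lay 243 bases inside CSF1R, a receptor gene of microglia, and next to the neighbouring gene PDGFRB, which starts at 150113839. In neurons, the regions named with the mirror pattern were 3902 bases outside MSX1 (chromosome 4, 4867839 to 4868334), 11815 bases outside NR4A2, a nuclear receptor gene of deep-layer neurons (chromosome 2, 156311919 to 156312621), and 15880 bases inside the netrin receptor gene UNC5D (chromosome 8, 35777217 to 35780660). The other neuron regions were 18277 bases inside MOXD1 (chromosome 6, 132382613 to 132383198) and 20885 bases outside TBP (chromosome 6, 170532808 to 170533483). All 10 lost their call when peaks had to cover 50% of the region, with adjusted Fisher p from 0.062 to 0.675. None lost it when a library was left out, but regions chosen for complete separation keep it there, so that step does not test them.

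At each stage the populations differed at more regions than the other splits of the same 4 libraries. At day 40, 19435 regions had a peak in both progenitor libraries and neither neuron library and 34272 the reverse, against 2121 and 3341 for the other splits in both directions together. At day 60 the counts were 31864 and 16030 (other splits 4749 and 2664), at day 90 27498 and 17049 (3288 and 2219), and at day 120 14778 and 21117 (4000 and 3431). An exact test of 1 region with 2 libraries against 2 cannot pass, so these are counts without a test. Which population had more followed the covered length, with means of 80.3 and 101 Mb at day 40, 82.4 and 69.1 Mb at day 60, 101 and 80.2 Mb at day 90, and 61.0 and 59.3 Mb at day 120 where the order was the opposite. With lists of equal length the counts were 18219 and 16392 at day 40, 20636 and 17762 at day 60, 17024 and 13965 at day 90, and 16795 and 19896 at day 120. Leaving out 1 library at a time raised them to as much as 63167 at day 40 (neurons, without neuron replicate 2), 57997 at day 60 (progenitors, without progenitor replicate 1), 41908 at day 90 (progenitors, without progenitor replicate 2) and 44155 at day 120 (progenitors, without progenitor replicate 2).

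Around genes, progenitors had more open chromatin over the lists of radial glia, astroglia and outer radial glia genes. Of 18755 loci, 1856 had higher scaled coverage in progenitors and 2089 in neurons (limma, adjusted over all genes). Without scaling the counts were 1025 and 653, so the share of calls on the progenitor side was 61.1% in place of 47.0%. A 2-group limma fit gave 2241 loci for this grouping, and 2251 for one that set day 40 neurons with progenitors of days 40, 60 and 90 and day 120 progenitors with the other neurons. In lists of equal length the 2 groupings gave 3603 and 1806. The loci called in the main fit were longer genes, with medians of 54.5 kb (higher in progenitors) and 45.9 kb (higher in neurons). Over all genes tested the median was 26.6 kb. Whether a call depends on gene length was not tested. The radial glia list, genes of the stem cells of the cortex, scored 1.28 ± 0.110 in progenitors and 0.842 ± 0.114 in neurons, a difference of 0.44 (n = 8 each, exact permutation p = 0.000155, adjusted p = 0.00124), and all 8 progenitor libraries lay above all 8 neuron libraries. Of its 20 members 11 were higher in progenitors and 0 lower (12 adjusted over the list alone), led by the growth factor receptor FGFR3 with a log2 difference of 1.18, SOX2, the Notch effector HES1 with 0.83 and the glutamate transporter SLC1A3 with 0.82. NES, the nestin gene, did not pass, with 0.30 and an adjusted p of 0.07. The astroglia list differed by 0.49 (exact adjusted p = 0.00186), and 6 of 11 members were higher in progenitors (6 higher and 1 lower adjusted over the list alone), led by the matricellular protein gene SPARCL1 with 2.01, S100B with 0.81, the connexin gene GJA1 with 0.69 and CD44 with 0.68. Outer radial glia, the basal stem cells that are abundant in human cortex, differed by 0.26 (exact adjusted p = 0.0170). There 5 of 10 members were higher (5 adjusted over the list alone), with 0.69 for PTN, 0.53 for FAM107A, 0.53 for ACSBG1 and 0.50 for TNC, although FAM107A stood at −0.10 at day 120. For this list alone the share of members with a peak at a gene end differed, 88.8% ± 3.54 in progenitors and 71.2% ± 3.54 in neurons (n = 8 each, exact adjusted p = 0.00746).

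The scores of the Notch, Hippo-YAP, proneural, late temporal and pluripotency lists were also higher in progenitors. The Notch pathway list differed by 0.36 (exact adjusted p = 0.00124), with 5 of 11 members higher and 1 lower in progenitors (7 and 1 adjusted over the list alone). Its largest differences were 1.12 for the receptor gene NOTCH2, 0.72 for MAML2, 0.71 for JAG1 and 0.69 for LFNG, and the effector HEY1 was lower at −0.42. The Hippo-YAP list, on the pathway that restrains tissue growth, differed by 0.27 (exact adjusted p = 0.00124) through 2 of 10 members (3 adjusted over the list alone), the coactivator genes YAP1 with 1.23 and WWTR1 with 0.77. Counted as peaks in place of bases, this score differed by −0.05 (exact adjusted p = 0.362). The intermediate progenitor and proneural list differed by 0.19 (exact adjusted p = 0.0032), with 4 of 12 members higher (4 adjusted over the list alone), among them NEUROD4 with 0.91, NEUROG1 with 0.60 and BTG2 with 0.47. Only 5 of the 12 members had a positive difference, and their median was −0.02, against −0.05 over all genes. The share of members with a peak at a gene end was 94.8% in progenitors and 100% in neurons (exact adjusted p = 0.205). With flanks of 5 kb this list's adjusted p was 0.722, and the difference of BTG2 was −0.21. The late temporal list, genes of late, gliogenic progenitors, differed by 0.43 (exact adjusted p = 0.00224), with 4 of 7 members higher (6 adjusted over the list alone). They were the transcription factor genes ZBTB20 with 0.62, NFE2L2 with 0.61, NFIA with 0.52 and SOX8 with 0.43. The pluripotency list differed by 0.26 (exact adjusted p = 0.0272) through 1 of 7 members (1 adjusted over the list alone), DPPA4 with 1.42, and no longer passed with lists of equal length (adjusted p = 0.123) or without any 1 of 5 libraries (progenitor day 40 replicate 2, 0.0533, progenitor day 60 replicate 2, 0.0518, neuron day 40 replicate 1, 0.0536, neuron day 60 replicate 1, 0.0589, and neuron day 90 replicate 1, 0.0586).

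Neurons had more open chromatin over the pan-neuronal list and the list of synaptic vesicle and release genes. The pan-neuronal list scored 1.12 ± 0.114 in progenitors and 1.39 ± 0.150 in neurons, a difference of −0.27 (n = 8 each, exact adjusted p = 0.00746). Of its 16 members 8 were higher in neurons (10 adjusted over the list alone), led by the neurofilament gene NEFM with −0.64, RBFOX3, which encodes the marker NeuN, with −0.59, the neuronal fate factor MYT1L with −0.56 and the synuclein gene SNCB with −0.53. The synaptic vesicle and release list differed by −0.19 (exact adjusted p = 0.0032), with 3 of 14 members higher in neurons (3 adjusted over the list alone), SYN2 with −0.95, the priming factor UNC13A with −0.94 and the active zone gene PCLO with −0.48. These 10 lists, 8 higher in progenitors and 2 in neurons, were the ones that passed, and each had the same direction at 4 of 4 stages. They passed a test that treats libraries as exchangeable, and splits that keep replicates together were not run for them. The housekeeping list leaned to neurons without passing, at −0.14 (exact adjusted p = 0.0671). Its median member stood at −0.17, against −0.13 in the synaptic vesicle and release list and −0.32 in the pan-neuronal list. The typical synaptic member thus moved no more than a housekeeping gene. The glutamatergic neuron list differed by −0.20 and missed the threshold (exact adjusted p = 0.0553), with 4 of 12 members higher in neurons and 2 in progenitors (5 and 2 adjusted over the list alone). The AMPA receptor gene GRIA2 had the largest difference, −1.18, followed by GRIN1 with −0.47, NEUROD2 with −0.41 and GRIN2A with −0.37. The ion channel list also missed it, at −0.21 (exact adjusted p = 0.0553), with 5 of 12 members higher in neurons (5 adjusted over the list alone), among them the sodium channel gene SCN3A with −0.49 and the calcium channel gene CACNA1C with −0.48.

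**Figure D3:**
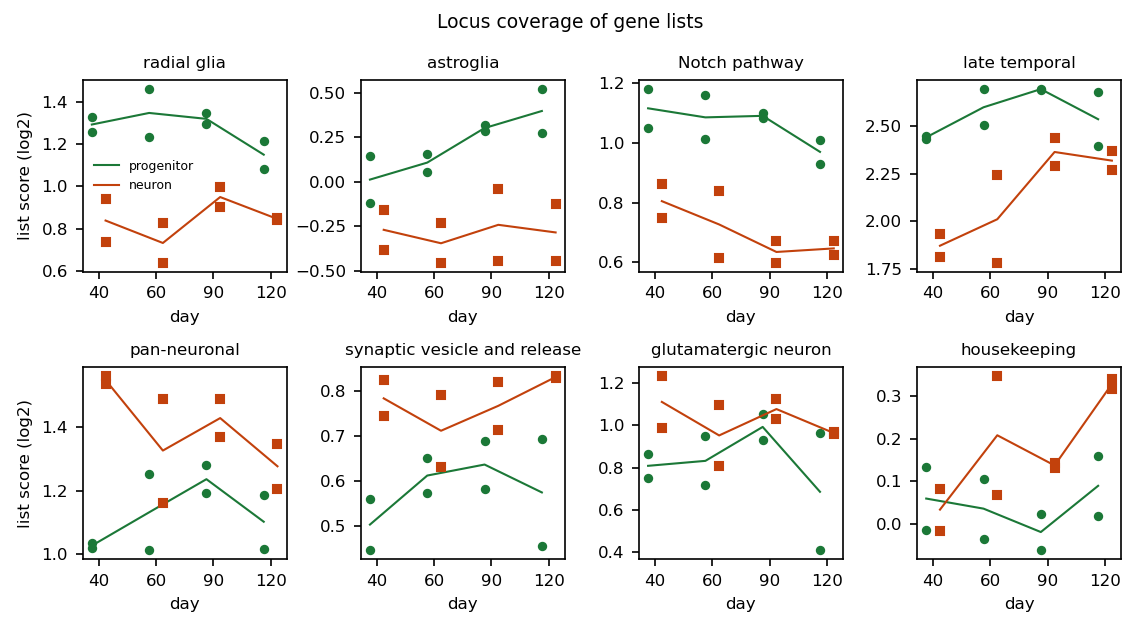
List score (log2, mean scaled locus coverage of the list minus that of all genes tested) against day (40, 60, 90 and 120, evenly spaced) for 8 gene lists, with single libraries as points, progenitors as green circles, neurons as orange squares and lines joining group means. Radial glia scores lay between 1.08 and 1.46 in progenitors and between 0.638 and 0.998 in neurons.

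Lists for cortical layers and for other cell types did not pass as wholes. The deep-layer list differed by −0.01 (exact adjusted p = 0.916), with FOXP2 at 0.67 and TLE4 at 0.30 higher in progenitors, and CRYM at −0.59 and ZFPM2 at −0.48 higher in neurons, 4 of 10 members in all (4 adjusted over the list alone). The upper-layer list differed by 0.03 (exact adjusted p = 0.755), with UNC5D at −0.43 higher in neurons, and RORB at 0.33 and POU3F3 at 0.30 higher in progenitors, among 4 of 10 members that passed (6 adjusted over the list alone). Axon guidance and adhesion differed by −0.11 (exact adjusted p = 0.432), with CNTN2 at −0.55, the netrin receptor gene DCC at −0.37 and UNC5C at 0.34 among 7 of 13 members that passed (9 adjusted over the list alone). Counted as peaks in place of bases, CNTN2 stood at 0.08 and POU3F3 at −0.05. The cell cycle list differed by 0.09 (exact adjusted p = 0.229), with CDC20 at 0.48 higher in progenitors and CENPF at −0.56 and MCM2 at −0.28 higher in neurons, 3 of 12 members (3 adjusted over the list alone). GABAergic and ventral genes differed by 0.22 (exact adjusted p = 0.150), with 5 of 13 members higher in progenitors (6 higher and 1 lower adjusted over the list alone), led by the neuregulin receptor gene ERBB4 with 0.73, GSX2 with 0.67, DLX1 with 0.50 and DLX2 with 0.36. The score of progenitor day 120 replicate 1 for this list, 1.23, stood apart from the other progenitor libraries.

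The remaining lists held at most 5 members that passed. The oligodendrocyte lineage list differed by 0.16 (exact adjusted p = 0.160), with GPR17 at 0.83 as 1 of 9 members (1 adjusted over the list alone), and choroid plexus and cortical hem by 0.22 (exact adjusted p = 0.238), with the transthyretin gene TTR at 0.88 and OTX2 at 0.48, 2 of 11 (2 adjusted over the list alone). Mesenchyme and fibroblast genes differed by 0.06 (exact adjusted p = 0.611), with the collagen gene COL3A1 at −1.24 and DCN at −0.64 higher in neurons, and PRRX1 at 0.63 and PDGFRB at 0.60 higher in progenitors, 5 of 9 members in all (5 adjusted over the list alone). Immune and endothelial genes differed by −0.03 (exact adjusted p = 0.716), with KDR at 0.66 as 1 of 10 members (1 adjusted over the list alone). Non-telencephalic neural genes differed by 0.26 (exact adjusted p = 0.279), with PAX3 at 0.90, TCF7L2 at 0.88 and PAX7 at 0.40, 3 of 11 (4 adjusted over the list alone). The early temporal list differed by 0.19 (exact adjusted p = 0.275), with IGF2BP3 at 0.26 as 1 of 7 members (0 adjusted over the list alone). Housekeeping genes differed by −0.14 (exact adjusted p = 0.0671), and 0 of 12 members passed in limma. Among the members named in these paragraphs, MCM2, NEUROD2, CRYM, TLE4, OTX2, PAX7 and IGF2BP3 lost their call in 8 to 14 of the 16 fits without 1 library, and CDC20, RORB and DLX2 in 2 or 3.

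Over all genes, the loci with the largest differences included SPARCL1 of the astroglia list and DIO2 in progenitors. DIO2, which encodes the deiodinase that activates thyroid hormone (chromosome 14, 80197526 to 80231057), had 1.98 ± 0.718 kb of peaks in progenitors and 0.0234 ± 0.0661 kb in neurons (n = 8 each), a log2 difference of 2.12 ± 0.20 (limma adjusted p = 7.26e-08). SPARCL1 (chromosome 4, 87473335 to 87529376) had 3.86 ± 0.908 kb and 0.720 ± 0.736 kb. SLCO1C1, a thyroid hormone transporter gene, differed by 1.94, the gluconeogenesis gene PCK1 by 1.98, the ceruloplasmin gene CP by 1.84, TREM1 by 1.83, HAPSTR2 by 1.79, the p63 gene TP63 by 1.78 and TEX101 by 2.18. PSG6 was listed with no covered bases in the 8 neuron libraries and 1.60 ± 0.743 kb in progenitors. In neurons, PHACTR3, a regulator gene of protein phosphatase and actin (chromosome 20, 59577509 to 59847711), had 8.67 ± 2.77 kb against 2.29 ± 1.18 kb in progenitors (n = 8 each), a difference of −1.80 ± 0.20 (limma adjusted p = 5.97e-07). OSTN, which encodes the secreted peptide osteocrin, differed by −1.92, the serpin gene SERPINI2 by −1.95, the orphan receptor gene GPR26 by −1.82, CCR3 by −1.72, CYP2C18 by −1.68 and GNAT3 by −1.66. KRTAP10-12 with −2.55, KRTAP10-4 with −1.70 and KRTAP19-7 with −1.69 belong to a keratin-associated family in tandem, as PSG6 belongs to one of its own, and their assignment is uncertain. The same direction at 4 of 4 stages was a condition for naming these 20 loci and is no result of its own. Without any 1 library their differences kept their direction, and the smallest was −1.44, for CCR3. Loci chosen for large differences in 1 direction can hardly lose that direction there, so this step does not test them.

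By stage, 820 loci were higher in progenitors and 426 in neurons at day 40, 503 and 629 at day 60, 206 and 254 at day 90, and 539 and 750 at day 120 (limma, adjusted over all genes). Differences between these counts were not tested, and neither their order nor the side with more calls was stable. Without scaling, which shifts the median of all genes, they were 45 and 132 at day 40, 108 and 20 at day 60, 41 and 5 at day 90, and 49 and 77 at day 120, and with median scaling 517 and 628 at day 40, 682 and 401 at day 60, 306 and 179 at day 90, and 740 and 497 at day 120. Single libraries of the stage moved the counts as well. At day 40 they were 167 and 135 without progenitor replicate 1, 209 and 165 without progenitor replicate 2, and 231 and 126 without neuron replicate 2, and 495 in progenitors without neuron replicate 1. At day 60 they were 131 and 146 without progenitor replicate 1, 183 and 232 without progenitor replicate 2, and 313 and 196 without neuron replicate 2. At day 90 they were 8 and 11 without progenitor replicate 1, 9 and 10 without progenitor replicate 2, and 14 and 15 without neuron replicate 2, and 96 in neurons without neuron replicate 1. At day 120 they were 177 and 231 without neuron replicate 1, 200 and 203 without neuron replicate 2, 909 in progenitors without progenitor replicate 1, and 319 in progenitors and 1185 in neurons without progenitor replicate 2. Leaving out either progenitor library of day 120 also raised the counts of other days through the shared spread, to as many as 1383 in progenitors at day 40, 1051 in neurons at day 60, and 326 and 578 at day 90. SOX2 had more coverage in progenitors at each of the 4 days.

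As progenitors aged, 4 of 7 early temporal genes and 4 of 11 genes of the choroid plexus and cortical hem list lost open chromatin. Late (days 90 and 120) against early (days 40 and 60), 271 loci rose and 274 fell (limma, adjusted over all genes). Their median gene lengths were 114 kb and 59.8 kb, against 26.6 kb over all genes tested. The early temporal list had 4 of 7 members that fell (4 adjusted over the list alone). They were the RNA-binding protein gene IGF2BP2, which fell by 0.79 ± 0.14 (limma adjusted p = 0.00317, 19.0 ± 3.0 kb early and 13.2 ± 9.95 kb late, n = 4 each), LIN28B, the repressor of let-7 processing, by 0.68, the chromatin protein gene HMGA2 by 0.63 and IGF2BP3 by 0.47. In the choroid plexus and cortical hem list 4 of 11 members fell (7 adjusted over the list alone), the morphogen genes BMP4 by 0.98 and WNT3A by 0.90, MSX1 by 0.60 and LMX1A by 0.53. Much of these differences arose within one of the age groups. Scaled coverage of IGF2BP2 averaged 14.02, 14.31, 13.99 and 12.76 from day 40 to day 120, so its fall lay at day 120, where 1 of the 2 libraries has the shortest list. The choroid plexus and cortical hem score averaged 0.33, −0.24, −0.26 and −0.41, so most of its difference lay between days 40 and 60, both early. Of the 16 pan-neuronal members, 3 rose and 1 fell, with 0.72 ± 0.12 for the migration gene DCX (limma adjusted p = 0.00188, 7.55 ± 1.5 kb early and 12.1 ± 3.59 kb late), 0.52 for ELAVL4, 0.51 for THSD7A and −0.45 for RBFOX3 (3 and 1 adjusted over the list alone). ITGB5 rose by 0.70, SEMA3A by 0.66, SCN3A by 0.71, CENPF by 0.68, CPLX2 by 0.52 and ZBTB20 by 0.50, while IRX1 fell by 1.05, CRIPTO by 1.18, CACNA1A by 0.95, AJUBA by 0.58, GRIA1 by 0.51, FGFR2 by 0.50 and DACH1 by 0.44. In the late temporal list ZBTB20 rose and FGFR2 fell, and the list score differed by 0.10 (exact p = 0.457, adjusted p = 0.686).

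These calls leaned on single libraries more than those between the populations. Without progenitor day 90 replicate 1, 50 loci rose and 54 fell, without day 120 replicate 1 411 rose, and without day 120 replicate 2 631 fell. Without progenitor day 40 replicate 1 the counts were 83 and 55, without day 40 replicate 2 121 and 106, without day 60 replicate 1 149 and 170, without day 60 replicate 2 92 and 68, and without day 90 replicate 2 78 and 79. LIN28B missed the threshold without day 40 replicate 1 (limma adjusted p = 0.0571) or day 90 replicate 1 (0.0754), HMGA2 without day 40 replicate 1 (0.0980), day 60 replicate 1 (0.0652) or day 90 replicate 1 (0.106), and BMP4 without day 90 replicate 1 (0.0560). DCX, ITGB5, SEMA3A and IGF2BP2 passed without any 1 library, CACNA1A and IRX1 were lost in 2 of the 16 fits, and the other members named were lost in 4 to 11. Both late means lay beyond both early means for 23 of these 25 list members, all but RBFOX3 and LMX1A. Without scaling 5 loci rose and 25 fell, and with median scaling 332 and 150. The median log2 change of all genes was −0.05 with the scaling used and −0.16 without scaling.

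As neurons aged, 5 of 7 late temporal genes gained open chromatin and 2 of 7 early temporal genes lost it. In limma, 618 loci rose and 445 fell from early to late neurons, with median gene lengths of 82.4 kb and 70.8 kb against 26.6 kb over all genes tested. Of the late temporal list, 5 of 7 members rose (6 adjusted over the list alone), led by ZBTB20, a repressor needed for hippocampal and glial fates, with 0.75 ± 0.12 (limma adjusted p = 0.000786, 23.7 ± 7.09 kb early and 32.5 ± 5.81 kb late, n = 4 each), NFE2L2 with 0.52, NFIX with 0.49 and NFIA with 0.46. NFIA averaged 14.10, 15.13, 15.22 and 14.94 from day 40 to day 120 and NFIX 13.43, 14.09, 14.13 and 14.37, so their difference lay mostly between the early days 40 and 60, whereas ZBTB20 averaged 14.37, 14.44, 14.99 and 15.31. In the early temporal list 2 of 7 members fell (3 adjusted over the list alone), IGF2BP2 by 0.79 ± 0.14 (limma adjusted p = 0.00144, 17.2 ± 5.37 kb early and 8.63 ± 4.72 kb late) and HMGA2 by 0.49. IGF2BP2 averaged 13.81, 14.08, 13.61 and 12.69, with most of its fall at day 120. Of the 10 upper-layer genes 2 rose (2 adjusted over the list alone), among them RORB by 0.53, and the 10 deep-layer genes had none that passed in limma, where ZFPM2 had the largest difference at −0.31. Of the 20 radial glia genes 2 rose, SLC1A3 by 0.80 ± 0.16 and FABP7 by 0.68 (4 rose and 1 fell adjusted over the list alone), and of the 10 outer radial glia genes 3 rose, PTN by 0.96, TNC by 0.57 and PTPRZ1 by 0.52 (3 adjusted over the list alone). In the Hippo-YAP list 1 of 10 rose, WWTR1 by 0.73 (1 adjusted over the list alone), and 0 of 11 astroglia genes passed in limma. The list scores differed by 0.11 for radial glia, 0.21 for outer radial glia, 0.12 for Hippo-YAP and 0.04 for astroglia (exact p of 0.2, 0.0286, 0.114 and 0.686). The radial glia score of neuron day 90 replicate 1, 0.998, was the highest of the 8 neuron libraries. Without this library TNC rose by 0.56 and PTPRZ1 by 0.47, close to their values with all libraries, although neither kept its call in that fit. Without any 1 library SLC1A3, FABP7, PTN and WWTR1 rose by at least 0.65, 0.65, 0.77 and 0.63. Among neuronal genes RBFOX3 fell by 0.60 ± 0.13, SYT1 by 0.46, the calcium channel genes CACNA1E by 0.60 and CACNA1C by 0.47, and GRIA1 by 0.51, while GRIA2 rose by 0.67. MBP, which encodes myelin basic protein, fell by 0.97 ± 0.16 (limma adjusted p = 0.000918), LMX1A by 0.77, IRX1 by 0.82 and PDGFRB by 0.64, and COL3A1 rose by 1.37, DCN by 0.93, ACTB by 0.68 and PPP1R17 by 0.64.

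Among these neuronal calls, ZBTB20, IGF2BP2, SLC1A3, FABP7, PTN, WWTR1, RBFOX3, CACNA1E, MBP and LMX1A passed without any 1 library. NFIA missed the threshold without neuron day 120 replicate 1 (limma adjusted p = 0.0594), and HMGA2, NFE2L2, NFIX, RORB and the others named were lost in 3 to 14 of the 16 fits. Over all genes, leaving out neuron day 90 replicate 1 left 236 loci that rose and 219 that fell, neuron day 40 replicate 2 271 and 172, neuron day 120 replicate 1 273 and 238, and neuron day 120 replicate 2 307 and 285. Without progenitor day 120 replicate 1 or replicate 2, which enter this contrast only through the shared spread, 1044 rose in either case. Without scaling 47 rose and 246 fell, against a median change of all genes of −0.20 in place of 0.06. Counted as peaks, ACTB stood at −0.20. Both late means lay beyond both early means for 26 of the 27 list members named here, all but NFIA.

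No list score passed between late and early, a comparison that could hardly pass. With 4 libraries against 4 the smallest possible exact p is 0.0286, and at least 14 of the 24 lists would have to reach it together. In progenitors the astroglia score changed by 0.29, immune and endothelial by 0.22 and pluripotency by −0.35 (exact p = 0.0286, adjusted p = 0.229 each), outer radial glia by 0.29 and choroid plexus and cortical hem by −0.38 (exact p = 0.0571, adjusted p = 0.274 each), and early temporal by −0.35 (exact adjusted p = 0.514). In neurons late temporal changed by 0.40 and outer radial glia by 0.21 (exact p = 0.0286, adjusted p = 0.343 each), early temporal by −0.33 and choroid plexus and cortical hem by −0.34 (exact adjusted p = 0.436 each). The choroid plexus and cortical hem score of neurons averaged 0.10, −0.49, −0.54 and −0.53 from day 40 to day 120, again with the step between the early days. The amount called did not differ detectably between late and early libraries, at 80.9 ± 30.3 Mb late and 81.4 ± 4.60 Mb early in progenitors (n = 4 each, exact p = 1) and 69.7 ± 12.4 Mb and 85.1 ± 22 Mb in neurons (exact p = 0.286).

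**Figure D4:**
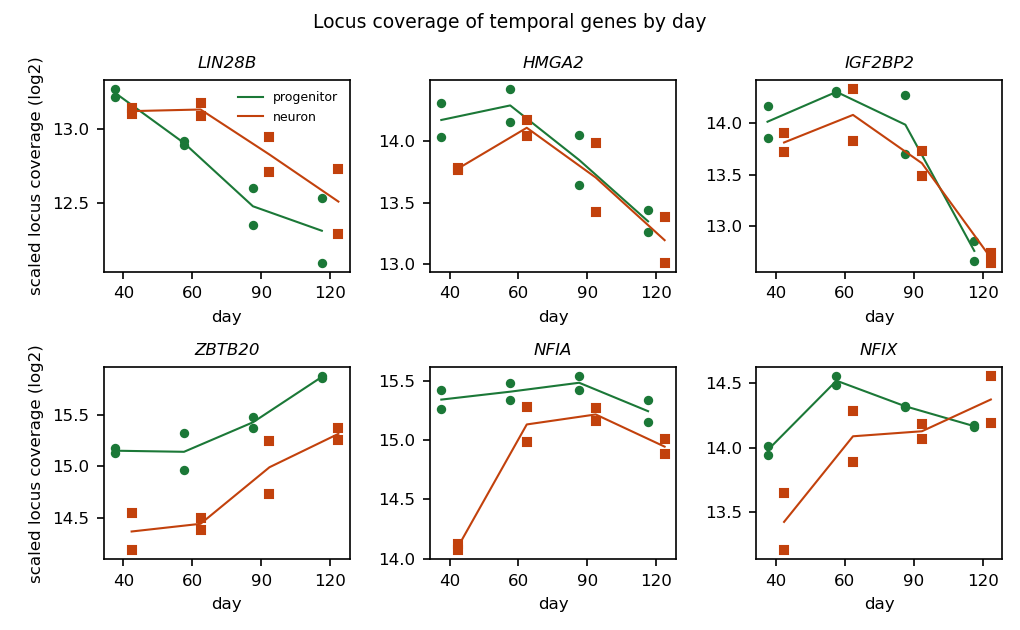
Scaled locus coverage (log2) against day (40, 60, 90 and 120, evenly spaced) for LIN28B, HMGA2, IGF2BP2, ZBTB20, NFIA and NFIX, with single libraries as points, progenitors as green circles, neurons as orange squares and lines joining group means. From early to late, IGF2BP2 fell by 0.79 in both populations, and ZBTB20 rose by 0.50 in progenitors and 0.75 in neurons.

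The loci with the largest changes over time were mostly sparsely covered, where the scaling itself moves values with the amount called. In late progenitors BLNK, a B cell linker gene, rose by 1.58 (0.124 ± 0.144 kb early and 1.29 ± 0.674 kb late), SLC22A2 by 1.65 and OR4M1 by 1.64, and RGPD4 and SUCNR1 were listed with no covered bases early. The proneural endocrine gene NEUROG3 fell by 1.70 (2.40 ± 0.704 kb early and 0.444 ± 0.641 kb late), the neurotrophin gene NTF3 by 1.63, LOC124904394 by 1.59 and SLFN13 by 1.56, and SLFN12 was listed with no covered bases late. In late neurons the receptor genes HCAR3 and HCAR2 rose by 2.54 and 2.34, NLRP10 by 2.21, ADGRG4 by 1.97 and CELA2A by 1.94 (1.3 ± 1.41 kb early and 4.31 ± 0.173 kb late). The estrogen receptor gene GPER1 fell by 2.05 (4.67 ± 2.15 kb early and 0.531 ± 0.409 kb late), ITGB6 by 1.81, MMP26 by 1.66, and ADIRF and the overlapping LOC124902474 by 1.64. The HCAR, SLFN, RGPD and olfactory receptor genes lie in families of near copies and are uncertain. Calls lost without single libraries were SUCNR1 in 13 of 16 fits, OR4M1 in 9, SLFN13 in 6, SLC22A2 in 5, SLFN12 and MMP26 in 3 each and BLNK without progenitor day 90 replicate 1 (limma adjusted p = 0.0714).

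Single regions that follow a split were most numerous for the split into late and early libraries, in both populations. Only 3 splits of a population keep the libraries of a stage together, too few to test the grouping of stages. In progenitors 1708 regions had a peak in all 4 late and no early library and 1582 the reverse, 3290 together, where the highest of the other splits of these 8 libraries gave 2525. In neurons 3971 regions were late-only and 856 early-only, 4827 together against 1551. Late-only regions of progenitors numbered 5294 without day 120 replicate 2, 2795 without day 60 replicate 1 and 2797 without day 90 replicate 2, and early-only regions 2892, 2437 and 3090 without day 60 replicate 1, day 60 replicate 2 and day 90 replicate 2. In neurons, late-only regions numbered 6870 without day 60 replicate 1 and 7830 without day 90 replicate 2. Early-only regions of neurons numbered 1428 without day 40 replicate 2, 1546 and 3809 without day 60 replicates 1 and 2, and 2305 without day 90 replicate 2, and 1299 without day 90 replicate 1. A count of regions that follow a split can only rise when a library is left out, since fewer libraries have to follow it.

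The change with age was compared between the populations, with calls that rested on few libraries and settings. In limma the change from early to late differed between progenitors and neurons at 118 loci. The signed change was the more positive one in progenitors at 49 and in neurons at 69. Among list members were DCX, with a difference of 0.79 (limma adjusted p = 0.033), FGFR2 with −0.86 (0.042), WNT2B and CACNA1E, and these 4 were named because they are the list members that passed. Leaving out 1 progenitor library gave 15 and 41 loci for the replicates of day 40, 32 and 42 for day 60, 33 and 39 for day 90, and 209 and 428 for day 120. Leaving out neuron day 40 replicate 2 gave 67, the replicates of day 90 36 and 71, and those of day 120 35 and 30. Without scaling 0 loci passed in limma, with 1161 at an unadjusted p under 0.05, and 3 passed with peaks in place of bases. No list score differed in its change over time (smallest exact adjusted p = 0.487).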

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

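The test of other splits of the samples was chosen after the result it measures was seen. Of 60 sets of values of 8 libraries, 6 had a library far from the others, with a gap to its nearest neighbour that was a large part of the whole range, where chance gives about 1 in 20. Progenitor day 120 replicate 2 had the shortest covered length of the progenitors, 36.9 Mb. The same library had the lowest non-telencephalic neural score of the progenitors, −0.332. Progenitor day 120 replicate 1 had the highest GABAergic and ventral score of the progenitors, 1.23, and their highest oligodendrocyte lineage score, 0.375. Neuron day 60 replicate 2, the shortest of the neuron lists at 54.8 Mb, stood apart from the other neuron libraries in its Hippo-YAP score, 0.249, and its upper-layer score, 1.22. None of these 6 values was weighed further.

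The change from early to late differed between the populations at 118 loci, by the limma test of the difference itself. A simpler limma fit, with age groups pooled over days, was repeated over 100 splits that regrouped the libraries by age within each population. There the real grouping gave 3 loci and the highest of the other splits 84, and 3 splits, the real one included, gave at least 3. With so few loci under the real grouping, chance is not excluded for the 118 loci, whose number also fell to 0 without scaling. A split with 84 loci points to a structure of the samples that late against early does not describe, and what that structure is was not tested.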

How the results depend on the processing

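The alternatives without the 2 shortest lists, with scaling before the pseudocount and with the amount called as a covariate were chosen after the data were seen, and the others before. Of the main results, 545 values under an alternative stayed the same and 207 moved, and of single genes and regions 8010 stayed the same, 833 no longer passed, 200 newly passed and 5 reversed. Peak number, covered length, gene-end share and the similarity of peak sets kept their result under every alternative run. The excess of similarity within populations lay between 0.105 and 0.126 without 1 library (highest exact p = 0.000311). The 10 list scores that passed kept their direction except where given here, and late against early, where 14 of 24 lists would have to reach the smallest exact p together, the absence of a passing list says nothing about stability (unadjusted exact p under 0.05 for 3 lists in progenitors and 2 in neurons). The number of lists past the threshold was 9 to 12 without 1 library, and 9 lists that did not pass passed in at least 1 alternative. Motif density and its GC weighting were not run, since no sequence was used here. The lists hold no read depth, so whether a missing peak reflects closed chromatin or a shallow library cannot be decided. Without 1 library a group has a lone sample, assumed to vary like the others. For the values below that moved or reversed, the cause was not tested, with these exceptions. Covering 50% of a region and a −log10 q of at least 3 leave fewer peaks to count. Leaving out libraries lets more regions follow a split. Blocks or strata raise the smallest p that a region can reach (0.00154 within stage and 0.00781 with the replicate block). For regions called between populations, leaving out the 2 shortest lists raises it too.

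For regions called between populations (5582 and 2318), 50% coverage gave 714 and 155, omission of the 2 shortest lists 3407 and 816, and −log10 q of at least 3 1337 neuron regions. Exact permutation within stage and with the replicate block gave 0 and 0 regions, with 19477 and 12720 at an unadjusted p under 0.05 within stage and 11732 and 6104 with the block (smallest adjusted p 0.107 and 0.320). Replicate numbers did not pair the libraries (r of −0.12, 0.21, 0.06 and 0.16 by day), and with the block limma called 1410 and 1503 loci. Without 1 library, 5696 to 8711 progenitor and 2339 to 3954 neuron regions were called.

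Regions of a stage with equal lists numbered 16392 (neurons, day 40), 20636 (progenitors, day 60) and 17024 (progenitors, day 90). With −log10 q of at least 3 they were 22745 (neurons, day 40), 9825 (neurons, day 60) and 9233 (progenitors, day 120), and with 50% coverage 7350 (progenitors, day 120) and 13247 (neurons, day 120). Without 1 library the ranges from day 40 to day 120 were 22456 to 33401, 34608 to 57997, 31649 to 41908 and 16954 to 44155 in progenitors, and 38153 to 63167, 18498 to 46823, 19926 to 36990 and 21607 to 36035 in neurons. Besides the libraries named in the results, progenitor day 40 replicate 1 gave 33401, neuron day 60 replicates 1 and 2 24334 and 46823, neuron day 90 replicates 1 and 2 36990 and 29079, progenitor day 120 replicate 1 23001 in progenitors and 36035 in neurons, and neuron day 120 replicate 1 34388.

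Late-only and early-only regions of progenitors were 1116 and 942 with −log10 q of at least 3 and 1007 and 830 with 50% coverage, and late-only regions 5294 without the 2 shortest lists. In neurons, 50% coverage gave 2644 late-only regions, −log10 q of at least 3 319 early-only regions, and omission of the 2 shortest lists 3809 early-only regions. Without 1 library they ranged from 1769 to 5294 and 1613 to 3090 in progenitors and from 4170 to 7830 and 928 to 3809 in neurons.

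For loci between populations (1856 and 2089), a pseudocount of 2000 bases gave 983 and 1089, no scaling 1025 and 653, equal lists 3347 in neurons, and omission of the 2 shortest lists 3286 in neurons. Without 1 library, 1448 to 2407 and 1618 to 3529 were called, the last without progenitor day 120 replicate 2. Loci that rose and fell late in progenitors (271 and 274) were 450 and 609 with equal lists, 162 and 69 with a pseudocount of 2000 bases, 5 and 25 without scaling, 120 and 162 by number of peaks, and 439 and 820 with the amount called as a covariate. Those that fell were 155 with −log10 q of at least 3, 431 with a flank of 50 kb, 150 by the median, 488 with scaling before the pseudocount and 1043 without the 2 shortest lists. The ranges without 1 library were 50 to 411 and 54 to 631. In neurons (618 and 445), −log10 q of at least 3 gave 359 and 296, a pseudocount of 2000 bases 395 and 163, no scaling 47 and 246, and the number of peaks 349 and 287. The amount called as a covariate gave 733 that fell, and omission of the 2 shortest lists 1466 that rose. Without 1 library the ranges were 236 to 1044 and 172 to 643. The 118 loci whose change differed between populations were 428 with equal lists, 60 with a pseudocount of 2000 bases, 69 by the median (43 larger in progenitors and 26 in neurons, against 49 and 69), 0 without scaling (1161 at an unadjusted p under 0.05 in limma), 3 by number of peaks, 270 with the covariate and 1641 without the 2 shortest lists. Without 1 library they ranged from 15 to 428, and 13 libraries moved them by over 1.5 times.

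Loci called at single days, progenitors before neurons (820 and 426, 503 and 629, 206 and 254, 539 and 750 from day 40 to day 120), were 45 and 132, 108 and 20, 41 and 5, and 49 and 77 without scaling, and 494 and 227, 186 and 368, 71 and 151, and 196 and 143 with a pseudocount of 2000 bases. By number of peaks they were 487 and 217 at day 40, 279 and 308 at day 60, and 86 and 77 at day 90. Equal lists gave 672 in neurons at day 40, 921 and 1025 at day 60, 620 and 861 at day 90, and 850 and 1230 at day 120. Omission of the 2 shortest lists gave 1889 and 763 at day 40, 464 and 860 at day 90, and 1994 in neurons at day 120. Median scaling gave 517 in progenitors at day 40, and 401 and 497 in neurons at days 60 and 120. In neurons at days 90 and 120, a pseudocount of 100 bases gave 147 and 1129 and scaling before the pseudocount 153 and 1259. The covariate gave 344 in progenitors at day 90 and 1416 in neurons at day 120, and −log10 q of at least 3 gave 444 in progenitors at day 40. Without 1 library the ranges were 167 to 1383, 131 to 676, 8 to 326 and 177 to 909 in progenitors, and 126 to 622, 146 to 1051, 10 to 578 and 203 to 1185 in neurons.

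Reversed values were −0.21 for BTG2 with flanks of 5 kb and, by number of peaks, 0.076 for CNTN2, −0.046 for POU3F3, −0.0502 for the Hippo-YAP score and −0.20 for ACTB in late neurons. Of 160 named loci that passed, 94 no longer did without scaling, 64 by number of peaks, 48 of 158 with −log10 q of at least 3, 46 with a pseudocount of 2000 bases, 41 by the median, 38 of 159 with equal lists, 28 with flanks of 50 kb and 27 of 155 with 5 kb, 18 with a pseudocount of 100 bases, 16 without the 2 shortest lists, 15 with the covariate, 14 with scaling before the pseudocount, 9 of 88 with the block and 3 without a filter. Without 1 library, 354 of 2560 such calls no longer passed. Of the list scores that passed, pluripotency no longer did with equal lists (adjusted p 0.123) or a pseudocount of 100 bases (0.0696), and the proneural list with flanks of 5 kb (0.722), all exact permutation tests.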

Other observations

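All tests of other splits, the amount called between populations and in single libraries, and the chromosome-end test were chosen after the results they measure were seen, whereas the other tests of the shared change with age and the list scores of the day 90 libraries were written first. Some loci were called with age in the same direction in both populations. In limma, 59 loci rose in both where 8.93 are expected if the calls were unrelated and the loci independent, and 57 fell in both where 6.50 are expected. Opposite calls numbered 5 and 1, with 6.43 and 9.03 expected. The overlap itself was not tested, and neighbouring loci share windows. ZBTB20, a repressor of neuronal fate programmes, rose in both, and the early timing genes IGF2BP2 and HMGA2, the hem gene LMX1A, IRX1, GRIA1 and RBFOX3 fell in both, genes taken from the fixed lists after their values were seen.

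Across 18755 genes, which are not independent replicates, the late minus early differences of the populations correlated with r = 0.299 (rho = 0.265). Technical explanations predicted that this would vanish under matched conditions, and the values were r = 0.278 in lists of equal length, 0.289 for genes more than 5 Mb from chromosome ends, and 0.33 for genes at least 500 kb apart, which argue against the amount called, chromosome ends and overlapping windows as the whole source. When the 8 neuron libraries were split in other ways, 1 of 35 splits, the real one, reached this r (highest other 0.281), and when the 8 progenitor libraries were split 4 of 35 did (highest other 0.307), so chance is not excluded. Only 3 splits of either population keep the libraries of a stage together, which is too few for a share under 0.05, and there the highest other r was 0.166 for neurons and 0.174 for progenitors (1 of 3 splits as large in each). A shared course of maturation may underlie the correlation, a hypothesis that these splits leave open.

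The differences between the populations were tested against other splits and against the amount called. Of 100 random splits only the real grouping reached its 2241 loci (1 of 100, highest other 91) and its 7900 regions (1 of 100, highest other 0). Libraries of a group are alike on average, and of the 35 splits that keep them together 1 reached the 7900 regions (highest other 719) but 2 reached the 2241 loci (highest other 2251). A share of 1 in 35 is the smallest these splits can give, and they were chosen after the data were seen. They argue against chance for the regions without excluding it, and this count does not do so for the loci. The split with 2251 loci, day 40 neurons with progenitors of days 40, 60 and 90, exchanges 1 group per side of the real grouping and has the largest difference in covered length of the 35 (23.8 Mb), but the next by covered length (23.7 and 22.6 Mb) gave 0 loci each in limma, so the source of its count stays open. In lists of equal length the real grouping gave 3603 loci and the highest other 1806 (1 of 35, the smallest share possible). This argues against chance for the loci without excluding it. In these lists 80.5% of the called loci were called again in the same direction, which argues against the amount called as the whole source. The shortened lists come from the same libraries, so this percentage says nothing about chance. The sorted cell type stays open as a source.

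Late against early, the splits were run with a 2-group limma fit that pools the days of an age group. There the real grouping gave 24 loci in progenitors, with 5 as the highest other of all splits (1 of 35). In neurons the real grouping gave 373, with 4 as the highest other (1 of 35). The main fit, with a mean for each population and day, had called 545 loci in progenitors and 1063 in neurons. The splits therefore bear on the smaller counts only. The real grouping gave 3290 and 4827 late-only and early-only regions, with 2525 and 1551 as the highest others (1 of 35 each). Replicates of a stage are more alike than other libraries on average, so these splits do not settle whether the grouping of stages matters. Only 3 splits keep stages together, too few for a share under 0.05, and their highest others were 1 and 4 loci and 2525 and 1350 regions (1 of 3 as large in each).

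Both populations had a day 90 library with many peaks at the other population's regions, taken as those with a peak in all 8 libraries of that population and in none of the remaining 7 of its own. Neuron day 90 replicate 1 had a peak at 23.7% of 2453 progenitor regions (other neuron libraries 1.73% to 15.6%) and progenitor day 90 replicate 2 at 31.8% of 792 neuron regions (other progenitor libraries 1.10% to 16%). The amount called predicts larger shares in longer lists, but neuron lists of 104, 97.9, 83.4 and 80.3 Mb had shares of 15.6%, 10.9%, 3.51% and 2.45%, below that of the neuron library with 80.0 Mb. In lists of equal length, however, its share was 8.02%, within the range of the others (0.975% to 12.5%), so the amount called and a real excess cannot be told apart for it. The progenitor library kept 21.6% (others up to 10.03%), which argues against the amount called there. The radial glia score of the neuron library, 0.998, was the highest of the neurons (next 0.940), and the pan-neuronal score of the progenitor library, 1.28, was the highest of the progenitors (next 1.25). Cells of the other population in the sort could give these values, and cells between the states that carry both reporters could too. The purity of the sort was not measured here, and no list separates these explanations.

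Loci near chromosome ends were frequent among those that fell late. Of the loci lower in late neurons 26.3% lay within 5 Mb of a chromosome end, and of those lower in late progenitors 21.2%, against 13.3% of all genes tested and 4.37% and 2.95% of those higher late, while a score for such loci differed late against early by −0.145 in neurons (exact permutation p = 0.0857) and −0.108 in progenitors (p = 0.257).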
